A study of Sus scrofa with 13 samples.

How the data were processed

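RNA-seq libraries of pig outflow vein came from 5 vehicle and 8 1,25 NP animals; per the labels' protocols 0.5 µg of total RNA entered a TruSeq V2 library. The labels' treatment protocol describes a mouse antibody experiment, and the submitters' processing notes name the mouse build mm10. Both contradict the organism and the pig Ensembl identifiers in the file, so neither was used, and the aligner, counter, pig build and annotation are not given in the sources used here. Coordinates are those of the file.

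The authors deposited a table of 30477 genes with an RPKM value per library, the authors' mean RPKM per group, a ratio of those means and an unadjusted p-value. The header gives no unit. The deposited values were taken as RPKM because value × (length + 1) × library total gave a whole number of reads for 100% of values within 0.001 reads. The library total was itself derived from the smallest values of each library. The check therefore cannot tell RPKM from another per-library scaling of reads per gene length. The deposited p-value column and fold ratio were recomputed and are the p of an equal-variance test on RPKM and the ratio of means, and other deposited columns of the table, such as gene length, were used for the recovery of reads only. Column names carry group, animal code and sex, with no replicate number, so columns were assigned to groups only. No column of per-sample values was left aside. Of 14012 rows with no symbol, 785 were named from a reference table of identifiers.

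The design fixed before the data were examined named a count model for count data and limma for normalized values. As the file holds RPKM, limma (version 3.58.1, R 4.3.3) was fitted with a mean-variance trend to log2(RPKM + 0.5) of the 14579 genes above 0.5 RPKM in at least 5 libraries, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of low genes. Mean ± SD values are in RPKM. The planned count models were not run. The test was checked on simulated data with 50 genes changed at each of 4 sizes. Of 50 genes, 26 were called at 2-fold, 39 at 4-fold, 42 at 8-fold and 45 at 16-fold, with 10 false calls among 162. The simulated spread between animals was set below the real one, most for genes with few reads, so these counts are too favourable.

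Gene lists written before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. Lists needed 5 tested members, which 26 of 29 had. They cover the vitamin D receptor and its targets, contractile smooth muscle, collagen and matrix, matrix proteases, inflammatory cytokines, TGF-beta and BMP signalling, cell proliferation, hypoxia, immediate early, interferon, apoptosis, oxidative phosphorylation, fatty acid oxidation, ribosomal proteins, the mitochondrial genome, heat shock, and markers of endothelium, lymphatic endothelium, macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells, fibroblasts, adipocytes, skeletal muscle, nerve, erythrocytes and platelets. Single measures were compared by two-sided exact permutation over all splits of the libraries. Named genes are VDR, CYP24A1 and IER3, the 5 smallest p-values in each direction with a symbol and a mean log2 CPM of at least 1, and up to 4 members per list with the smallest p. Values of 2 list members are not reported here.

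Library totals recovered from the values, taken as reads on genes, ranged from 30261776 to 50271231. Intervals reflect the spread between animals. Overlapping features can share reads: 8 genes with a mean of at least 100 reads fell into 4 groups with identical reads in every library. The kit's strand setting is not given in the sources used here, so reads of overlapping and antisense genes are uncertain.

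Alternatives were other scaling, filters, pseudocounts, weights, covariates and each library left out. Figures were drawn with matplotlib 3.10.9 in Python.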

Results

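The series profiled RNA from the outflow vein of arteriovenous fistulas in pigs, the vessel segment that receives arterial flow after an artery is joined to a vein for haemodialysis access. Vehicle animals received PLGA, a biodegradable polymer, in a hydrogel (5 libraries), and treated animals received the same material loaded with 1,25-dihydroxyvitamin D3 (8 libraries, called 1,25 NP). The hormone acts through the nuclear vitamin D receptor. The comparison asked which transcripts of the vein differed between treated and vehicle animals. The library totals recovered from the values were between 30261776 and 50271231 reads, and between 12970 and 14686 genes lay above 0.5 RPKM. Libraries are named by group and by the animal code in the deposited header, which also gives the sex: 3 females and 2 males among vehicle animals, 3 females and 5 males among treated ones. The Y-linked gene KDM5D was at most 0.00419 RPKM in the libraries marked female and at least 5.29 RPKM in those marked male.

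The genes with the smallest p-values among those higher in 1,25 NP veins included the cytokinesis scaffold ANLN, at 5.14 ± 1.80 RPKM (SD, n = 5) in vehicle and 13.3 ± 7.06 (SD, n = 8) in 1,25 NP veins, a log2 difference of 1.19 (SE 0.34). The tropomyosin TPM4 had 147 ± 32.8 RPKM in vehicle and 285 ± 111 in 1,25 NP veins, and the dynein light chain DYNLL1 had 17.96 ± 4.52 and 36.3 ± 13.3 RPKM. CDK2AP1, an inhibitor of a cell cycle kinase, had a log2 difference of 0.66 (SE 0.21), as had CCDC34 (SE 0.21), which was low in vehicle at 0.461 ± 0.0848 RPKM. All 8 treated libraries lay above the vehicle mean for ANLN, TPM4, CCDC34 and CDK2AP1, and 7 of 8 did for DYNLL1. None of these 5 genes passed the test across all genes (limma, adjusted p = 0.795 for each). Over the alternative settings the differences ran from 0.47 to 1.25 for CCDC34 and from 0.41 to 0.78 for CDK2AP1. They ran from 0.41 to 1.02 for TPM4, 0.62 to 1.08 for DYNLL1 and 0.91 to 1.44 for ANLN.

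Among the genes lower in 1,25 NP veins, the smallest p-value belonged to MYBPC3, a myosin-binding protein best known from heart muscle (ENSSSCG00000013236, chromosome 2, 15247539 to 15270104 in the coordinates of the file). It had 2.80 ± 1.03 RPKM in vehicle and 0.831 ± 0.361 in 1,25 NP veins, a log2 difference of -1.28 (SE 0.26), with all 8 treated libraries below the vehicle mean. SFRP5, a secreted Wnt antagonist, had 3.78 ± 2.47 RPKM in vehicle and 0.659 ± 0.316 in 1,25 NP veins, a log2 difference of -1.64 (SE 0.40). The sodium pump subunits ATP1A4 and ATP1B2 had log2 differences of -1.19 (SE 0.29) and -0.84 (SE 0.22), and NT5DC3 had -1.44 (SE 0.38). ATP1A4 ranged from 1.12 to 4.30 RPKM in vehicle and from 0.128 to 1.01 in 1,25 NP veins. None of the 5 passed with all libraries (limma, adjusted p = 0.795). Over the alternative settings the differences ran from -1.51 to -0.59 for ATP1B2 and from -1.86 to -0.85 for ATP1A4. They ran from -1.86 to -1.02 for MYBPC3, -2.20 to -1.21 for SFRP5 and -1.65 to -1.01 for NT5DC3. Without vehicle library P17, where SFRP5 was at 0.456 RPKM against 2.72 to 6.52 in the other 4 vehicle libraries, SFRP5 passed (limma, adjusted p = 0.0487, log2 difference -2.11). NT5DC3 was at 23.9 RPKM in that library and at 3.59 to 6.29 in the other 4, and without it the difference was -1.01 (limma, adjusted p = 0.974).

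Across the 14579 genes tested, limma called 0 genes at an adjusted p of 0.05, with 585 at an unadjusted p under 0.05 (117 higher and 468 lower in 1,25 NP), where 729 would be expected by chance. limma voom on the recovered reads also called 0 genes, with 629 at an unadjusted p under 0.05, and voom with sample quality weights called 0, with 1914. The median standard error of a log2 difference was 0.33, so the median 95% interval reached 1.63-fold to either side of the estimate. In data simulated on these libraries, in which genes varied independently, the same test called 52% of genes changed 2-fold and 78% of genes changed 4-fold. The simulated spread between animals was below the real one, most for genes with few reads. These shares therefore overstate what the test could find here. The authors' deposited table holds 27174 p-values, of which 1139 were under 0.05 before adjustment, and 0 of the deposited p-values passed a Benjamini-Hochberg adjustment (smallest adjusted value 0.790).

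The receptor of the drug and its textbook targets were measured next. VDR, the vitamin D receptor, had 3.19 ± 3.02 RPKM (SD, n = 5) in vehicle and 3.89 ± 2.34 (SD, n = 8) in 1,25 NP veins, a log2 difference of 0.51 (SE 0.53, limma, adjusted p = 0.795). The VDR difference was 0.12 without vehicle library P15, 0.21 without vehicle library P17, 0.33 without 1,25 NP library P23 and 0.92 without vehicle library P16, and it was 0.057 in voom with sample quality weights. IER3, an immediate early gene known to be lowered through VDR, had 1.67 ± 0.690 and 2.22 ± 1.51 RPKM (log2 difference 0.20, SE 0.37, limma, adjusted p = 0.855). With 1 library left out the IER3 difference ran from 0.029 (1,25 NP library P32) to 0.36 (1,25 NP library P22), and it was -0.13 with the skeletal muscle list as covariate. CYP24A1, the enzyme that degrades the hormone and its classical target gene, lay below the filter: 24 reads in 1 of 5 vehicle libraries (P16) and 35 reads in 6 of 8 treated libraries, 24 of them in 1,25 NP library P31. The difference was -0.00779 on the log2 scale (two-sided exact permutation p = 0.988), 0.083 without vehicle library P16 and -0.059 without 1,25 NP library P31. Of the 16 tested members of the list of the vitamin D receptor and its targets, 7 were higher and 9 lower in 1,25 NP veins and 0 passed, also when adjusted over the list alone. The median was -0.16 while camera gave the upward direction (adjusted p = 0.894), and without vehicle library P16 it was 0.073, with 10 of 16 higher. The smallest p-values in it belonged to LRP5 (3.11 ± 2.42 and 2.29 ± 3.52 RPKM) and the cell cycle inhibitor CDKN1A (12.6 ± 7.80 and 18.4 ± 11.2 RPKM).

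**Figure D1:**
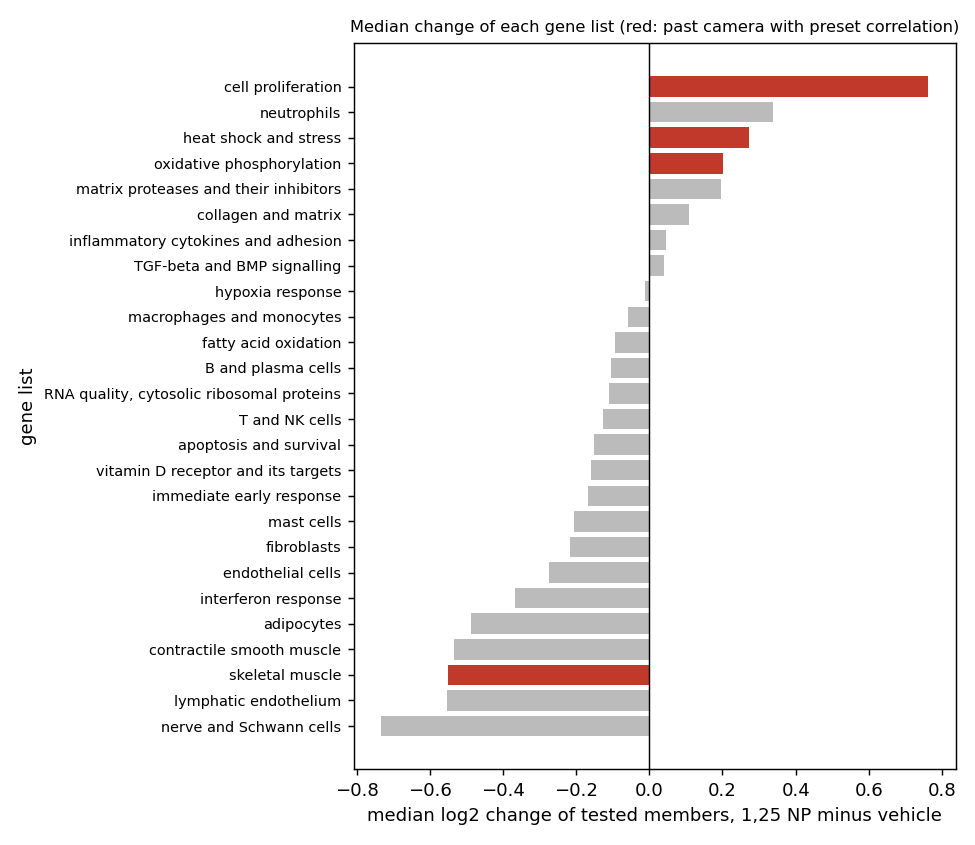
Median log2 change, 1,25 NP minus vehicle, of the tested members of each of the 26 gene lists with at least 5 tested genes (horizontal axis in log2 units). Red bars are the 4 lists past camera with a preset correlation, which had medians of 0.76 (cell proliferation), 0.27 (heat shock), 0.20 (oxidative phosphorylation) and -0.55 (skeletal muscle).

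Cell proliferation genes rose as a list: 24 of 25 measured members were higher in 1,25 NP veins, with a median log2 change of 0.76 (camera, adjusted p = 3.31e-12). The call was lost with an estimated correlation (adjusted p = 0.888 with an estimated correlation), and 0 members passed singly, also when adjusted over the list alone. Over the list alone 16 of 25 passed without 1,25 NP library P28, 1 without vehicle library P14 and 10 in voom with sample quality weights, with 0 past the test across all genes in each. By sex the median was 1.39 in females (3 vehicle, 3 treated) and 0.14 in males (2 vehicle, 5 treated), and the difference of list means between the sexes did not pass (two-sided exact permutation p = 0.252, adjusted p = 0.553). CENPE, a mitotic kinesin, had 1.93 ± 1.26 RPKM in vehicle and 7.40 ± 4.51 in 1,25 NP veins. The mitotic cyclin CCNB1 had 3.08 ± 1.67 and 9.22 ± 6.69 RPKM, the thymidylate synthase TYMS 3.54 ± 2.62 and 6.72 ± 2.26, and the spindle protein TPX2 5.10 ± 2.07 and 12.3 ± 7.66. The list mean per library was 1.73 ± 0.490 (SD, n = 5) in vehicle and 2.45 ± 0.730 (SD, n = 8) in 1,25 NP veins, a difference that did not pass (two-sided exact permutation p = 0.0839, adjusted p = 0.839 over 30 measures). 1,25 NP library P28 had the lowest list mean of all libraries, 1.18 against 1.27 to 2.30 in vehicle, so leaving it out favours a rise. It was at 0.488 RPKM for CENPE, against 0.656 to 3.56 in vehicle.

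Genes of oxidative phosphorylation rose as a list, with 21 of 27 members higher and a median of 0.20 (camera, adjusted p = 0.00723; adjusted p = 0.996 with an estimated correlation). The estimated inter-gene correlation of this list was 0.45, also far above the preset 0.01. The median was 0.10 without vehicle library P13, with 17 of 27 higher, and 0.13 without 1,25 NP library P32. It was 0.35 without vehicle library P16 and 0.33 without 1,25 NP library P28. The complex I subunits NDUFB5 (2.99 ± 0.856 and 5.43 ± 2.52 RPKM) and NDUFA4 (42.5 ± 16.5 and 82.5 ± 48.6 RPKM) were among the smallest p-values, with UQCRFS1 and NDUFB3. Heat shock and stress genes rose as a list, with 9 of 15 higher and a median of 0.27 (camera, adjusted p = 0.0406; adjusted p = 0.996 with an estimated correlation). The chaperones HSPA5, at 98.9 ± 16.7 and 178 ± 107 RPKM, and HSPH1, at 5.78 ± 2.05 and 14.6 ± 11.2 RPKM, led it, followed by DNAJA1 and HSPE1. In both lists 0 members passed singly or adjusted over the list alone. Without the filter on low values 1 of each passed over the list alone, and its direction is not given here. For heat shock that setting had 9 members higher and 7 lower, against 9 and 6 with the filter. With the filter 0 heat shock members had an unadjusted p under 0.05 in limma. These passes are therefore not counted as part of a rise. Without vehicle library P15 neither list passed (camera, adjusted p = 0.112 for oxidative phosphorylation and 0.259 for heat shock). Heat shock was also lost without vehicle library P14 (camera, adjusted p = 0.0870), 1,25 NP library P22 (0.0676) and 1,25 NP library P28 (0.133), without the filter on low values (0.220), and with the skeletal muscle (0.103) or adipocyte list (0.0558) as covariate.

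Skeletal muscle genes fell as a list, with 0 of 5 members higher and a median of -0.55 (camera, adjusted p = 0.0362; adjusted p = 0.494 with an estimated correlation). The 5 members are low or shared with other tissues: TNNC1, a slow-muscle troponin, had 1.81 ± 2.12 RPKM in vehicle and 0.458 ± 0.489 in 1,25 NP veins, MYBPC2 had 0.689 ± 0.267 and 0.327 ± 0.254, and the glycogen phosphorylase PYGM had 17.2 ± 5.18 and 11.7 ± 1.83. CA3 had 2.71 ± 3.37 and 3.72 ± 9.27 RPKM, a higher treated mean beside a log2 difference of -0.64, and 1,25 NP library P42 was far above the other treated libraries. The list mean was 1.35 ± 0.135 in vehicle and 0.745 ± 0.449 in 1,25 NP veins (two-sided exact permutation p = 0.0186, adjusted p = 0.559). The call held for the 5 members past the filter only: without the filter 14 of 22 members were lower (median -0.071, camera, adjusted p = 0.741), and with a filter of 1 CPM in 5 libraries, which kept 14765 genes, 6 of 7 (median -0.51, 0.0948). It was also lost without vehicle library P15 (camera, adjusted p = 0.110) and without 1,25 NP library P28 (0.133).

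**Figure D2:**
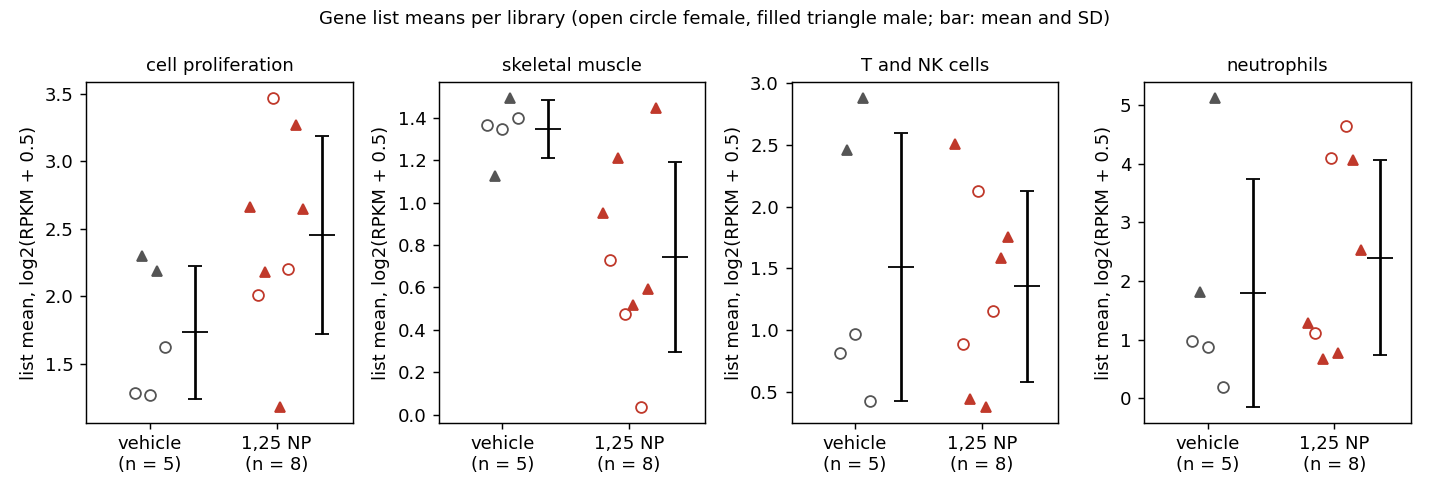
Mean log2(RPKM + 0.5) per library of 4 gene lists, with open circles for females, filled triangles for males and bars for the group mean and SD. The proliferation mean ranged from 1.27 to 2.30 in vehicle and from 1.18 to 3.47 in 1,25 NP libraries.

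Genes of nerve and Schwann cells lay just outside the test, with 8 of 10 lower and a median of -0.73 (camera, adjusted p = 0.0559; adjusted p = 0.996 with an estimated correlation). The median was -0.21 without vehicle library P15 (camera, adjusted p = 0.484), while the list passed with median-of-ratios scaling (0.0202), without the filter (0.0126) and with a filter of 1 CPM in 5 libraries (0.0145), which kept 12 members. With an estimated correlation the list did not pass in any of these settings. PRX, a protein of myelinating Schwann cells, had 1.71 ± 1.59 RPKM in vehicle and 0.420 ± 0.375 in 1,25 NP veins. PRX was at 4.43 RPKM in vehicle library P15 and at 0.453 to 1.501 in the other 4. Of the erythrocyte list 3 of 9 members in the table passed the filter, too few for the list test. Without the filter all 9 were lower, with a median of -0.79 (camera, adjusted p = 0.000456; adjusted p = 0.965 with an estimated correlation). The globin HBB had 915 ± 1864 RPKM in vehicle and 33.7 ± 18.7 in 1,25 NP veins, and the haem synthesis enzyme ALAS2 28.0 ± 58.4 and 0.611 ± 0.340. HBB was at 4248 RPKM in vehicle library P17 and at 15.2 to 142 in the other 4, and without that library its log2 difference was -1.17. All 3, with GYPC, passed in limma when adjusted over these 3 alone and 0 passed over all genes. Without the filter 0 of the 9 members passed when adjusted over the list alone. Without vehicle library P17, and with the filter, only ALAS2 passed over the 3 (limma, adjusted p = 0.0482), with 0.0957 for HBB and GYPC. Of the platelet list 3 members passed the filter (without it, 5 of 6 lower, camera, adjusted p = 0.546), and its smallest p-value belonged to ITGA2B, at 8.82 ± 1.65 and 7.55 ± 1.33 RPKM.

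Lists of the vessel wall did not pass. Contractile smooth muscle genes had 19 of 21 members lower with a median of -0.53 (camera, adjusted p = 0.134), including MYH11 at 247 ± 339 and 119 ± 153 RPKM and LMOD1 at 14.99 ± 21.5 and 7.73 ± 14.98. Without vehicle library P17, 12 of 21 were lower with a median of -0.061 (camera upward, adjusted p = 0.547). Without that library the median was also -0.045 for matrix proteases and -1.30 for lymphatic endothelium. Collagen and matrix genes had 17 of 31 higher with a median of 0.11 and a mean of 0.0046 (camera, adjusted p = 0.273). VCAN, a matrix proteoglycan, had 61.6 ± 16.8 and 110 ± 49.1 RPKM. Matrix proteases and their inhibitors had 16 of 27 higher (median 0.20, adjusted p = 0.352), TGF-beta and BMP signalling 18 of 33 (median 0.040, adjusted p = 0.273) and fibroblast markers 5 of 15 (median -0.22, adjusted p = 0.891). MMP11 had 11.9 ± 6.85 and 6.93 ± 6.42 RPKM, ID1 3.23 ± 1.40 and 5.88 ± 4.97, and CFD 21.4 ± 12.2 and 12.4 ± 13.2. With 1 library left out the medians ran from -0.11 to 0.22 for collagen and from -0.066 to 0.15 for TGF-beta and BMP signalling, and the fibroblast median was -0.015 without 1,25 NP library P31. Endothelial markers had 6 of 20 higher (median -0.27, adjusted p = 0.280) and lymphatic endothelium 1 of 7 (median -0.55, adjusted p = 0.339). The lymphatic median was -0.17 without vehicle library P15 and -0.30 without vehicle library P14. The endothelial median was -0.17 without 1,25 NP library P31. The endothelial marker ICAM2 had 5.56 ± 1.38 and 4.08 ± 1.03 RPKM, and FLT4, a receptor of lymphatic endothelium, 6.28 ± 4.50 and 2.65 ± 2.07.

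Leukocyte lists did not pass either. Macrophage and monocyte markers had 9 of 21 higher, with a median of -0.058 while camera gave the upward direction (adjusted p = 0.894). Within it the chemokine receptor CX3CR1 had 1.72 ± 0.628 and 3.74 ± 1.57 RPKM (limma, adjusted p = 0.795). Neutrophil markers had 4 of 5 higher (median 0.34, adjusted p = 0.411), and S100A8 was at 116 RPKM in vehicle library P16 and at most 1.51 in the other 4. T and NK cell markers had 5 of 17 higher (median -0.13, adjusted p = 0.894), with GNLY at 5.77 ± 5.07 and 2.60 ± 1.11 RPKM. B and plasma cell markers had 1 of 7 higher (median -0.10, adjusted p = 0.524), with CD22 at 4.68 ± 2.80 and 2.63 ± 1.27, and mast cell markers 2 of 5 (median -0.21, adjusted p = 0.894). Inflammatory cytokine and adhesion genes had 14 of 28 higher, with a median of 0.045, a mean of -0.026 and the downward direction by camera (adjusted p = 0.961). Without vehicle library P16 the medians were 0.29 for macrophages, 0.77 for neutrophils, 0.28 for T and NK cells, 0.087 for B and plasma cells and 0.21 for cytokines. The neutrophil median was -0.11 without vehicle library P17, and without vehicle library P14 those of T and NK cells and mast cells were 0.18 and 0.17. Among cytokine and adhesion genes NFKBIA, the inhibitor of NF-kappaB, had 68.9 ± 34.7 and 34.0 ± 7.98 RPKM.

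For the remaining lists camera gave adjusted p-values of 0.155 for the interferon response (3 of 23 higher, median -0.37), 0.524 for the hypoxia response (10 of 22, median -0.013, mean 0.060) and 0.750 for apoptosis and survival (7 of 21, median -0.15). They were 0.991 for the immediate early response (9 of 22, median -0.17, upward by camera), 0.962 for fatty acid oxidation (6 of 19, median -0.093) and 0.891 for adipocytes (3 of 7, median -0.49). For cytosolic ribosomal proteins the value was 0.891 (8 of 20, median -0.11). Without vehicle library P17 the interferon response had 14 of 23 higher and a median of 0.13 (camera upward, adjusted p = 0.481). Without vehicle library P16 the medians were 0.13 for hypoxia, 0.030 for the immediate early response and -0.21 for adipocytes. With 1 library left out in turn they ran from -0.15 to -0.012 for fatty acid oxidation. For apoptosis and survival they ran from -0.21 to -0.071. PDK4, which restrains glucose oxidation, had 17.4 ± 17.4 and 4.60 ± 2.79 RPKM, and the immediate early factor KLF2 7.30 ± 1.76 and 4.43 ± 1.79. Over the 26 lists 0 were past fry and 0 past camera with an estimated correlation, with 4 past camera at the preset correlation.

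None of the measures of library composition below passed between the groups, which with 5 and 8 libraries does not show that the groups were alike. Small nucleolar RNA genes took 6.84% ± 2.95 (SD, n = 5) of the reads in vehicle and 8.92% ± 4.73 (SD, n = 8) in 1,25 NP libraries (two-sided exact permutation p = 0.414), and the highest share was 17.8% in 1,25 NP library P31. The 50 most abundant genes took 33.3% ± 7.92 and 33.5% ± 7.43 (two-sided exact permutation p = 0.960). Protein-coding genes took 88.0% ± 3.73 and 85.9% ± 5.20 (two-sided exact permutation p = 0.462). All 37 mitochondrial genes, the 13 of the RNA quality list included, were listed at 0 in every library. The first principal component carried 48.3% of the variance of the 500 most variable genes and ran from -44.6 in 1,25 NP library P28 to 36.4 in 1,25 NP library P31 (group difference, two-sided exact permutation p = 0.396).

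**Figure D3:**
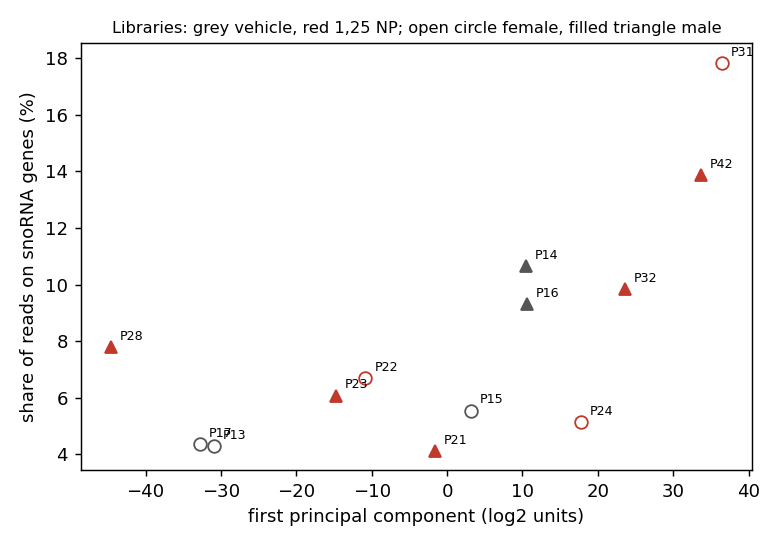
First principal component (horizontal axis, log2 units) against the share of reads on small nucleolar RNA genes (vertical axis, percent) for the 13 libraries, with animal codes, grey for vehicle and red for 1,25 NP. Small nucleolar RNA genes were not taken out of this component, so part of the relation may be built in. The relation tested further below uses a component on protein-coding genes alone. 1,25 NP libraries P31 and P42 have the largest shares, 17.8% and 13.9%, and both groups span the component.

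The header's sex letters allowed sexes to be compared across groups. With treatment in the model 14 genes differed by sex (limma, Benjamini-Hochberg 0.05), 12 of them higher in males and all 12 on the Y chromosome, including KDM5D and EIF1AY. No gene's treatment effect differed by sex after adjustment: limma called 0 genes, with 425 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0606.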

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

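All tests in this part were chosen after the results were seen, except the counts of splits for genes at an unadjusted p under 0.05 and for gene lists.

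Real and other splits of the 13 libraries into 5 and 8 were compared over 100 splits, the real one included. For genes past the test the real count was 0, which every split reaches, so this count (100 of 100, highest other 2) decides nothing. Of the 100, 33 gave at least 585 genes at an unadjusted p under 0.05 (highest other 6333). For gene lists past camera at the preset correlation, 84 of 100 gave at least 4 (highest other 19). Chance cannot be excluded for the last 2 counts, and the split with 6333 genes points to a structure among the libraries that the groups do not follow.

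Proliferation genes were higher in 1,25 NP veins, and 7 of 100 splits gave this list a camera p as small as the real 1.27e-13 (smallest other 5.89e-22), so chance cannot be excluded. Library scaling as the whole cause is argued against by median-of-ratios scaling, under which the median log2 change was 0.85 against 0.76 (camera, adjusted p = 4.49e-11; adjusted p = 0.473 with an estimated correlation). With that scaling the 95% interval of the list mean was 0.14 to 1.46. For more males among treated animals, sex in the model left the median at 0.72 (camera, adjusted p = 8.94e-10, and 0.880 with an estimated correlation). The median of T and NK cells went from -0.13 to -0.33. The proliferation list mean was 1.17 higher in treated than vehicle females, against 0.14 in males. For more leukocytes in treated veins, the macrophage and neutrophil lists in the model left the proliferation median at 0.62 (camera, adjusted p = 1.71e-14, and 0.591 with an estimated correlation). The median of macrophages went from -0.058 to -0.28, but this list is part of the covariate, so its shift tests nothing. Most of the proliferation median remained with either, but neither is excluded as a cause. Camera at the preset correlation cannot decide it, as the estimated correlation of the list was 0.66. The 95% interval of the list mean included 0 before (-0.0999 to 1.54) and with sex (-0.21 to 1.54) or leukocytes (-0.035 to 1.27) in the model. The list mean also followed the first principal component on protein-coding genes (r = 0.72, and 0.74 within 1,25 NP). A difference in tissue make-up between animals, not tested separately, stays open as well. Treatment remains a hypothesis beside these and chance.

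The first principal component spread libraries within both groups. On protein-coding genes alone it followed the small nucleolar RNA share (Pearson r = 0.66, permutation p = 0.0109, adjusted 0.0109 over 4 relations; Spearman rho = 0.65, permutation p = 0.0182), but r was 0.46 without 1,25 NP libraries P31 and P42, so the relation rests partly on them and stays open. It also followed the neutrophil list (r = 0.84, permutation p = 0.00044, adjusted 0.00176; rho = 0.85, permutation p = 0.00052; r = 0.82 without the 2 farthest libraries). Members of the neutrophil list were not taken out of the genes that define the component, so this is no independent test. Sex (two-sided exact permutation p = 0.545) and treatment (two-sided exact permutation p = 0.389) cannot be told apart from no effect here, because the standard errors of the differences were 12.8 and 12.9, against 22.6 for the SD within treatment groups. A candidate explanation is a difference in tissue make-up between animals, which was not tested separately.

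T and NK cell markers had a lower treatment effect in males than in females, by -1.92 in the list median (camera, adjusted p = 5.14e-10; adjusted p = 0.295 with an estimated correlation). The list mean was 0.736 in vehicle and 1.39 in 1,25 NP females, and 2.67 and 1.33 in males. Of the 420 reassignments of treatment within sex, a share of 0.031 gave a difference as large (two-sided exact permutation, adjusted p = 0.260 over 26 lists), so chance stays open; the adjusted value was added to this criterion after the unadjusted one had been seen. A single library as the cause is argued against: the difference of list means was -1.99, and the smallest with 1 library left out was -1.62, without 1,25 NP library P24. With 2 vehicle males, a sex difference may also be one between few animals.

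For 11 more lists camera at the preset correlation called a treatment effect that differed by sex, given as the male minus female median. They were -3.61 for neutrophils, -1.21 for cell proliferation, -1.19 for B and plasma cells, -0.86 for macrophages, -0.80 for matrix proteases, -0.77 for the hypoxia response, -0.72 for oxidative phosphorylation and -0.66 for inflammatory cytokines. They were 1.598 for contractile smooth muscle, 1.57 for nerve and Schwann cells and 0.47 for TGF-beta and BMP signalling. With an estimated correlation 0 of the 12 passed. T and NK cells did not stand out by reassignment of treatment within sex. The two-sided exact permutation p was smaller for matrix proteases (0.0119) and the hypoxia response (0.0238). It was 0.0429 for neutrophils and 0.05 for B and plasma cells, with an adjusted p of 0.260 for each of these 4 lists.

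In 15 of 222 groups of values 1 library lay far from the others, where chance gives about 1 in 20, or 11.1. Values are log2(RPKM + 0.5). Vehicle library P17 was high for NT5DC3 (4.61), the interferon-induced USP18 (4.33) and PYGM (4.75). Vehicle library P16 was high for S100A8 (6.87), S100A12 (7.21) and the macrophage list mean (5.68). Vehicle library P15 was high for the nerve list mean (3.85). 1,25 NP library P28 was high for LRP5 (3.50) and PNPLA2 (3.19) and low for FAP (2.91) and CENPE (-0.017). 1,25 NP library P31 was low for PI16 (3.18) and the fibroblast list mean (5.16). 1,25 NP library P42 was high for CA3 (4.76) and the adipocyte list mean (5.20).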

How the results depend on the processing

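Settings were planned except voom and its scaling for genes, robust variance, sex, leukocyte and protein-coding scaling, a pseudocount of 0.1 and the removal of 1,25 NP libraries P31 and P42, which were chosen after seeing the data, as were settings planned for genes and then run for lists. The count of 0 genes past limma held in every setting run except without vehicle library P17, which gave 1 (SFRP5), so the range with 1 library left out was 0 to 1. At an unadjusted p under 0.05 the count ran from 71 with the skeletal muscle list as covariate to 2213 without 1,25 NP library P28. The 4 lists past camera became 7 with median-of-ratios scaling and 8 without 1,25 NP libraries P31 and P42, and ranged from 1 without vehicle library P15 to 10 without vehicle library P16. It was also 9 without vehicle library P13, 8 without vehicle library P17 and 7 without 1,25 NP library P42, and the cause was not tested. Cell proliferation passed in all 29 alternatives (median 0.61 to 1.05), oxidative phosphorylation in 28, skeletal muscle in 23 and heat shock in 21, and with an estimated correlation 0 lists passed in any. Median-of-ratios scaling moved the median of all genes from -0.071 to 0.016. The group difference in the share of reads on the 50 most abundant genes, 0.22 percentage points, was -0.046 for the 10 most abundant and ranged from -1.72 to 3.42 with 1 library left out. No paired analysis was possible because the columns carry animal codes and no replicate number, and no code occurs in both groups. The labels number the libraries within each group, and nothing in the sources used here pairs vehicle with treated animals. A replicate number in the columns would therefore not by itself have made the comparison a paired one. The filter planned as a stricter one, 1 CPM in 5 libraries, kept 14765 genes against 14579, so no stricter filter was run. The planned count models were not run because the file holds RPKM, and library size alone is already the scaling of RPKM.

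Log2 changes or list medians that were not called changed sign under some settings, and the cause was not tested. Some were far from 0: with the skeletal muscle list as covariate adipocytes (from -0.49, camera, adjusted p = 0.00463) and inflammatory cytokines (0.0170) passed with the sign of the median turned. Neither passed with an estimated correlation (camera, adjusted p = 0.925 for both). With median-of-ratios scaling the change or median was 0.0863 for hypoxia response, 0.0461 for macrophages and monocytes, 0.01002 for fatty acid oxidation and 0.00354 for CYP24A1. With voom with quality weights it was 0.10 for vitamin D, -0.0253 for collagen and matrix, 0.26 for interferon response, 0.0719 for macrophages and monocytes, 0.0461 for fibroblasts, 0.0793 for fatty acid oxidation and 0.0293 for ribosomal proteins. With the skeletal muscle list as covariate it was -0.13 for IER3, -0.0749 for collagen and matrix, -0.0553 for matrix proteases, -0.30 for inflammatory cytokines and adhesion, 0.0199 for hypoxia response, 0.0133 for lymphatic endothelium, -0.70 for neutrophils, 0.33 for fibroblasts, 0.81 for adipocytes, 0.16 for nerve and Schwann cells, 0.11 for fatty acid oxidation and 0.10 for ribosomal proteins. With the adipocyte list as covariate it was 0.00371 for hypoxia response, 0.019 for macrophages and monocytes and 0.0436 for mast cells. With voom it was 0.0343 for hypoxia response. With voom with median-of-ratios scaling it was 0.14 for hypoxia response, 0.0562 for macrophages and monocytes, 0.0137 for B and plasma cells and 0.00531 for fatty acid oxidation. With sex as covariate it was -0.016 for inflammatory cytokines and adhesion. With scaling to protein-coding reads it was 0.0231 for hypoxia response. Without 1,25 NP libraries P31 and P42 it was -0.00456 for IER3, -0.0299 for matrix proteases, -0.22 for inflammatory cytokines and adhesion, 0.00963 for hypoxia response, 0.067 for immediate early response and 0.0206 for fatty acid oxidation. With a pseudocount of 0.1 it was 0.00324 for hypoxia response and 0.0104 for CYP24A1. With the leukocyte lists as covariate it was -0.10 for inflammatory cytokines and adhesion.

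With 1 library left out in turn, such values ranged from -0.28 to 0.0729 for vitamin D, -0.11 to 0.22 for collagen and matrix, -0.0453 to 0.36 for matrix proteases, -0.21 to 0.21 for inflammatory cytokines and adhesion, -0.0657 to 0.15 for TGF-beta and BMP signalling, -0.15 to 0.13 for hypoxia response and -0.28 to 0.0296 for immediate early response. They ranged from -0.64 to 0.13 for interferon response, -0.23 to 0.29 for macrophages and monocytes, -0.11 to 0.77 for neutrophils, -0.44 to 0.28 for T and NK cells, -0.42 to 0.0867 for B and plasma cells, -0.52 to 0.17 for mast cells, -0.18 to 0.00959 for ribosomal proteins and -0.0589 to 0.0827 for CYP24A1.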

Other observations

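Blood and nerve genes each had 1 library far above the rest, chosen here after their values were seen. In vehicle library P17 HBB was at 4248 RPKM and ALAS2 at 132 RPKM, against 15.2 to 142 and 0.357 to 3.34 in the other 4 vehicle libraries and 4.97 to 65.9 and 0.293 to 1.25 in the 8 treated ones. Without it the log2 differences were -1.17 for HBB and -0.97 for ALAS2 (limma, adjusted p = 0.974 for both). In vehicle library P15 PRX was at 4.43 RPKM, against at most 1.05 in any treated library, and without it the log2 difference was -0.76 (limma, adjusted p = 0.599).

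Leaving out 1,25 NP library P28, which lies at the negative end of the first component, raised the number of genes at an unadjusted p under 0.05 from 585 to 2213, with 0 past the test (limma, smallest adjusted p = 0.322, CENPE).

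Leaving out 1 library also brought lists past camera at the preset correlation that did not pass with all 13, and 0 of these passed with an estimated correlation. Without vehicle library P16 these were contractile smooth muscle (median -0.85, adjusted p = 0.00120), macrophages (0.29, 0.0138), neutrophils (0.77, 0.0138), nerve (-0.84, 0.0170), matrix proteases (0.36, 0.0301) and hypoxia (0.13, 0.0328). Without vehicle library P17 they were lymphatic endothelium (-1.30, 1.98e-05), nerve (-0.91, 0.00198), B and plasma cells (-0.42, 0.0359) and TGF-beta and BMP signalling (0.15, 0.0359). Without vehicle library P13 they were interferon (-0.64, 0.000332), collagen (0.22, 0.000332), TGF-beta and BMP signalling (0.061, 0.0292), nerve (-0.71, 0.0415) and matrix proteases (0.080, 0.0499). Without vehicle library P14 they were interferon (-0.46, 0.0274) and nerve (-0.67, 0.0342). Without 1,25 NP library P42 they were nerve (-0.82, 0.0129), collagen (0.094, 0.0346) and adipocytes (-0.54, 0.0346). Single lists passed without 1,25 NP libraries P22 (contractile, -0.64, 0.0477), P23 (nerve, -0.71, 0.0226), P24 (interferon, -0.48, 0.0307), P28 (contractile, -0.83, 0.00203) and P32 (collagen, 0.15, 0.0445).

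The first component on protein-coding genes was set beside 4 measures over the 13 libraries, chosen after the component was seen. Besides the 2 given with the tests, the proliferation list mean had r = 0.72 (permutation p = 0.00573, adjusted 0.00764 over 4; rho = 0.69, permutation p = 0.0107), with r = 0.70 without the 2 farthest libraries and 0.74 within 1,25 NP. The contractile list mean had r = -0.76 (permutation p = 0.00168, adjusted 0.00336; rho = -0.66, permutation p = 0.0164), with r = -0.52 without the 2 farthest libraries and -0.74 within 1,25 NP. Within 1,25 NP (n = 8) r was 0.59 for the small nucleolar RNA share and 0.84 for the neutrophil list, without a test. Members of the gene lists were not taken out of the genes that define the component. The p-values of the gene lists therefore do not test independent relations.

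Lists that did not pass with the settings of the report also passed camera under other settings, 0 of them with an estimated correlation. Contractile smooth muscle passed with median-of-ratios scaling (median -0.44, adjusted p = 0.0434), with voom at that scaling (-0.57, 0.0308), and with the skeletal muscle (-0.72, 2.74e-06) or adipocyte list (-0.65, 0.0243) as covariate. Nerve also passed with voom at median-of-ratios scaling (-0.83, 0.0252), and the interferon response passed with median-of-ratios scaling (-0.26, 0.0376). Without 1,25 NP libraries P31 and P42 nerve (-0.63, 0.00847), adipocytes (-0.45, 0.00847), collagen (0.13, 0.00847) and TGF-beta and BMP signalling (0.13, 0.0240) passed. With a pseudocount of 1 and no filter, B and plasma cells (-0.13, 0.0441), nerve (-0.41, 0.0167) and erythrocytes (-0.64, 0.000645) passed. With that setting heat shock was lost (0.23, 0.225), as was skeletal muscle (-0.038, 0.758).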
